A study of Homo sapiens with 314 samples.

How the data were processed

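Single cells of the esophageal squamous cell carcinoma line KYSE-180, irradiated to 0, 12 or 30 Gy in total, were lysed and amplified with a Smart-seq2 kit and made into Illumina libraries, per the labels' protocols. The series has 314 samples, 41 at 0 Gy, 184 at 12 Gy and 89 at 30 Gy. The 184 samples at 12 Gy are labelled as 2 replicates of 92 cells, and both labels of a cell name the same column, so each column was used as 1 cell. All 222 columns were used.

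The authors deposited 1 table of counts, whole numbers of reads for 22456 genes under versioned Ensembl identifiers. Reads were aligned with TopHat2 2.0.14 and analysed with DESeq2, per the submitters' processing notes, and Monocle is also named in the series' design text. The genome build, the annotation, the read counter, its use of strand and its treatment of reads with several placements are not given in the sources used here. The table is named as normalized, per the labels, but its values behaved as raw counts. Each was a whole number, column totals ran from 4792 to 2918309, and no column skipped a value from 1 to 15. Size factors recomputed over the 76 genes above 0 in every cell ran from 0.00364 to 5.15, where normalized values would give about 1. The deposited values were therefore treated as read counts and scaled between cells here. The choice of main scaling was made after this was found, since the design, fixed before the data were examined, took the values as already normalized.

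Cells were scaled with pooled sum factors (scran 1.30.0 in R 4.3.3) from genes other than mitochondrially encoded ones, with doses as clusters and a minimum mean of 1. A normalized count is a read count divided by the cell's factor. The value of a gene at a dose is the mean over its cells, and the log2 ratio of a pair of doses used a pseudocount of 1 on each mean, which understates the ratios of low genes. Depth sets precision: the 3 doses had 85174500, 91242142 and 34131465 reads in total, and the floor of 3 reads over a dose equals means of 0.038, 0.0285 and 0.0791 normalized counts at 0, 12 and 30 Gy. A ratio to a dose without reads is given as a bound against that floor.

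Each dose is 1 sample, because the labels name no separate cultures, so no test was run and cells were not used as replicates. The 30 gene lists and the rule for named genes were fixed in advance. Named genes are the 12 highest and 12 lowest by log2 ratio among genes that passed 2 filters. At the dose with the higher mean they had a mean of at least 20 and reads in at least 25% of cells. They were also at least 2-fold apart in the same direction in odd-numbered and even-numbered cells. Pseudogenes, clone-named and small RNA genes were left out, and up to 4 members with the largest ratios were taken from each list. A few genes picked by these rules are not reported here. Where the 12 lowest had no reads at 30 Gy, the next 12 over 100000 bases away from genes low at 30 Gy are given too, and likewise genes that entered in gene-rich cells. Both additions were chosen after the values were seen.

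List medians used expressed members, with a mean of at least 1 and reads in at least 10% of cells at the dose with the higher mean. Random lists were matched in 20 bins of mean expression. Per-cell scores are means of log2(normalized count + 1) over a list. Some listed genes were not analysed here, among them KRT14, IFI44L, CXCL3, SOD2, XBP1 and most cornified envelope genes. Of 23 squamous differentiation genes 13 were in the table, and the list's medians used the 9 expressed in each comparison. Of the fibroblast, leukocyte, and endothelial and erythroid markers 4, 4 and 3 were in the table. A further 5 lists with lipid, metallothionein and EGFR ligand genes were added after the values were seen. Genes low at 30 Gy were defined, also after the values were seen, as at least 8-fold lower than at both other doses where both means reached 10, and genes within 100000 bases of them were called near.

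Gene symbols came from the identifiers, for 21997 genes. Positions are those of GENCODE 29 (GRCh38), held for 22137 genes, and are not the authors' coordinates. Reads of near-identical copies, as among keratins, metallothioneins, histones, HLA genes, ribosomal proteins and the NPIPB and NBPF families, could be split between genes, and reads of overlapping or antisense genes such as UGDH-AS1 could not be told from their partners. Doublets were not called, since the protocol amplified cells 1 by 1.

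The steps were tested on simulated counts drawn from the real means and library sizes. At a simulated 4-fold difference, 48 to 50 of 50 genes passed the rule of 2-fold in both sets of cells, and 6 to 17 of 50 did at 2-fold. Of 6895, 6889 and 6874 unchanged genes, 0, 1 and 0 passed in the 3 comparisons. Apart from the changed genes, all simulated cells shared 1 mean profile. The simulation held no cells with few genes for their depth, no cell cycle and no difference between cultures or batches. These counts therefore do not give the rate of false passes in the real data. Alternatives were other scalings (totals, median-of-ratios, rescaling to the median gene), thinning to 100000 reads, summed reads, means of log2 values, a mean trimmed by 10%, other pseudocounts (0.1 and 10), other filters on list members, odd-numbered or even-numbered cells, gene-rich cells and leaving out genes near those low at 30 Gy. Calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9.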

Results

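The series measured RNA in single cells of KYSE-180, an established cell line grown from a human esophageal squamous cell carcinoma. The cells came from cultures that had received a cumulative irradiation of 12 Gy, 30 Gy or none (0 Gy), and the series concerns resistance to radiation. Each library was made from 1 cell by Smart-seq2, which amplifies whole transcripts by PCR and carries no molecular identifiers. The table held 41 cells at 0 Gy, 92 at 12 Gy and 89 at 30 Gy, with reads for 22456 genes. The labels name no separate cultures within a dose, so each dose counts as 1 sample, no replicate check exists, and no p-value is given. Values after ± are SDs over cells. Bracketed 95% intervals are exact Poisson intervals for summed reads and exact Clopper-Pearson intervals for shares of cells, and both cover counting error only, since PCR reads are not independent molecules.

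Depth differed strongly between the doses. Reads per cell had a median of 2055198 at 0 Gy (range 1062567 to 2918309), 825338 at 12 Gy (4792 to 2740278) and 357107 at 30 Gy (22236 to 1405115). The median number of genes detected per cell was 11291, 11406 and 9847. After thinning every cell to 100000 reads it was 8374, 8700 and 8243, with 0, 3 and 3 cells too shallow to enter. Mitochondrially encoded genes took a median of 16.5%, 18.1% and 16.8% of the reads. At 12 Gy 4 cells and at 30 Gy 1 cell were sparse, with under 50% of the median of 10746 genes over all cells. The other cells are called gene-rich here. Dose and library batch, as far as column naming shows one, could not be separated, because each dose had its own naming.

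**Figure D1:**
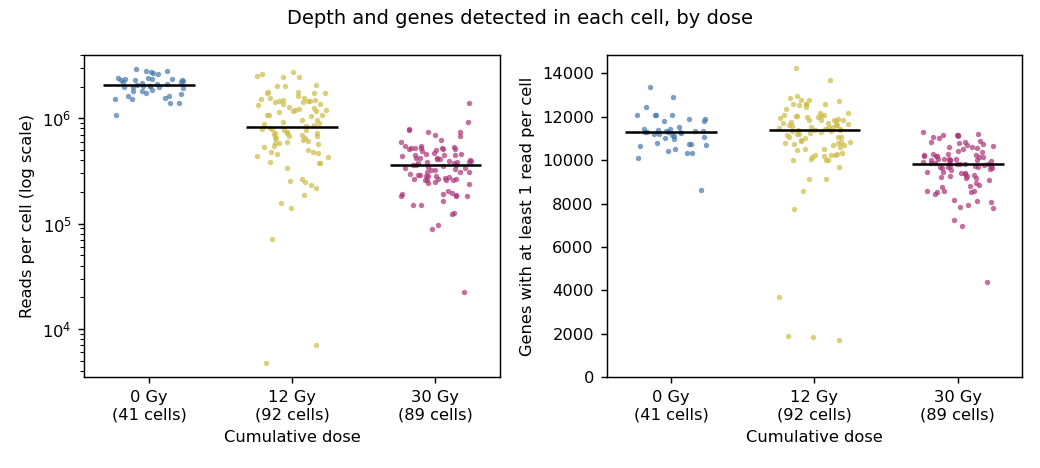
Reads per cell (log axis) and genes detected per cell (linear axis) by dose, where each point is 1 cell and the line marks the median. Median reads per cell were 2055198, 825338 and 357107 at 0, 12 and 30 Gy.

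Ratios between doses depended on how cells were scaled. The median log2 ratio over expressed genes was -0.03 at 12 Gy against 0 Gy, -0.05 at 30 Gy against 0 Gy and 0.00 at 30 Gy against 12 Gy. Scaling each cell to its total moved these medians to 0.22, 0.19 and -0.02, and median-of-ratios size factors moved them to 0.42, 0.26 and -0.15. For this reason "higher" and "lower" of a gene group below mean relative to the median expressed gene, and a group is given no direction where that relative value changed sign among the 6 scalings tried. The relative value cancels any factor common to a dose, so rescaling to the median gene barely alters it. Totals, thinning and summed reads also gave similar medians, so the 6 scalings are not independent checks, and a kept sign is weak support. The ratio also varied with expression. Genes with means of at least 10 at both 0 and 12 Gy had a median of -0.20 at 12 Gy against 0 Gy. A list of abundant genes can therefore lie below the median expressed gene without lying below genes of like expression. The percentile of a group, which allows for this, is that of its median among 10000 random lists of the same size and matched expression.

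Cells that had received 12 Gy were first compared with unirradiated cells. The highest genes included a metallothionein and a keratin of stressed epithelium, and the lowest included genes of lipid synthesis and EGFR ligands. Among the lists, basal squamous genes were higher at 12 Gy, and immediate early and G1/S genes were lower. MT1X, a metal-binding metallothionein (chromosome 16, 56682424 to 56684196 in GENCODE 29, GRCh38), had a mean of 21.4 ± 20 normalized counts at 12 Gy and 0.393 ± 0.718 at 0 Gy, a log2 ratio of 4.00. It had reads in 95.7% of cells (89.2 to 98.8) at 12 Gy and 39% (24.2 to 55.5) at 0 Gy, from 2333 (2239 to 2430) and 30 (20 to 43) summed reads. SCD, the desaturase that makes oleic acid (chromosome 10, 100347124 to 100364834), had 17.7 ± 31.9 normalized counts at 12 Gy and 128.6 ± 84 at 0 Gy, a log2 ratio of -2.79.

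Among the 12 highest genes, MAB21L3 had a log2 ratio of 4.13. KRT17, a keratin induced in wounded epithelium (chromosome 17, 41619441 to 41624842), had 88.5 ± 140.7 normalized counts at 12 Gy and 5.09 ± 10.1 at 0 Gy, a log2 ratio of 3.88. INHBA, a subunit of the growth factor activin A, reached 37.2 ± 167.3 against 1.82 ± 6.23 (3.76). The chemokine CXCL14 had a log2 ratio of 3.47, with 91.8% of its 12 Gy signal in 10 cells. SULT1B1, a sulfotransferase, had 2.76, and 1.77 in gene-rich cells, where it was no longer among the 12 highest. The remaining 6 highest genes also depended on the 4 sparse cells, so 5 of the 12 were shared with gene-rich cells. SPINK9, C22orf46P, ACAP1, TMEM212, TMED2-DT and HNRNPL had log2 ratios of 5.88, 5.79, 5.69, 5.12, 4.07 and 2.88 in all cells, and 1.12, 0.62, 1.16, 2.77, 1.49 and 1.39 in gene-rich cells. In gene-rich cells NAV2 (2.55), SEMA3B (2.49), the calprotectin subunit S100A9 (2.30), TMC4 (2.25), the glucose transporter SLC2A3 (2.22), the metallothionein MT1F (2.19) and IL32 (2.16) entered the 12 highest instead.

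Of the 12 lowest genes at 12 Gy, 11 were also among the 12 lowest in gene-rich cells. EREG and AREG, both ligands of the EGF receptor, had log2 ratios of -2.83 and -2.05. EREG had 11 ± 27.1 normalized counts at 12 Gy, 84.1 ± 107.7 at 0 Gy and 34.7 at 30 Gy. DUSP1, a phosphatase that switches off MAP kinases, had 57.1 ± 97.2 at 12 Gy, 309 ± 245 at 0 Gy and 224 at 30 Gy (-2.42 against 0 Gy). The selenoprotein gene SELENOW had 80.5 ± 47.7 against 389.7 ± 103.5 (-2.26). INSIG1, a feedback regulator of cholesterol synthesis, STARD4, a sterol carrier, and SC5D, a late enzyme of cholesterol synthesis, had -2.12, -2.12 and -2.02. The prostaglandin E2 receptor PTGER4 (-2.07), CCDC9B (-1.94), the complement regulator C4BPB (-1.88) and CCN2, a matricellular growth factor (-1.88), completed the set.

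In the G1/S and replication list, 19 of 20 genes lay below 0 at 12 Gy, with a median of -0.64 (percentile 0.2, and -0.62 to -0.56 relative to the median expressed gene over the scalings). The S-phase cyclins CCNE2 (-1.47) and CCNE1 (-1.05) and the histone mRNA binding protein SLBP (-1.10) were lowest, and the licensing factor CDT1 (0.94) was the exception. G2/M and mitosis genes had a median of -0.40 (percentile 44.1), with 15 of 20 below 0 and relative values of -0.48 to -0.34. Among them were the mitotic kinases PLK1 (-0.83) and AURKA (-0.82). CDK inhibitor and senescence genes had a median of 0.21 (93.2), led by IGFBP3 (1.01) and CDKN2B (0.74). Replication-dependent histones had -0.46 (2.3), with relative values of -0.51 to -0.15 and H2AC6 at -1.31.

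Genes of the response to DNA damage differed little at 12 Gy. The 23 expressed p53 targets had a median of 0.01 (percentile 69.2), with 12 above and 11 below 0. CDKN1A, the p53-induced CDK inhibitor, had 54.3 normalized counts at 12 Gy and 53 at 0 Gy, while SESN2 (0.97) and PHLDA3 (0.92) lay above 0 and TIGAR (-1.10) below. Double-strand break repair and checkpoint genes had a median of -0.12 (69.5), with the end-joining ligase LIG4 at -1.27, XRCC5, which encodes Ku80, at -0.68 and BRCA1 at 0.61. Pro-apoptotic genes had -0.29 (10.1), with CYCS, which encodes cytochrome c, at -1.29. Anti-apoptotic genes had -0.40 (18.6), with BIRC3 at -0.90 and CFLAR at 2.12, or 0.84 in gene-rich cells.

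Basal squamous genes had a median of 0.98 (percentile 100) at 12 Gy, with 8 of 11 above 0, 0.53 in gene-rich cells and relative values of 0.45 to 1.07 over the scalings. ITGA6, a laminin receptor subunit of basal cells, had 78.4 ± 108.2 against 25.7 ± 26.4 normalized counts (1.57), KRT15 had 1.65, and COL17A1 had 1.24 in all cells but -0.07 in gene-rich cells. TP63, the master regulator of squamous epithelium, had reads in 17.4% (10.3 to 26.7) of 12 Gy cells and 4.88% (0.596 to 16.5) of 0 Gy cells. Stress keratins had a median of 1.97 (100), with KRT6A at 1.97 and KRT16 at 0.35, although reads of these closely related copies, like those of metallothioneins and HLA genes, are uncertain. Epithelial junction genes had 0.21 (100), with KRT19 at 1.00, the desmosome gene DSP at 0.87 and CLDN1 at -0.83. Squamous differentiation genes had a median of -0.28 (4.7) without a direction over the scalings (relative values of -0.26 to 0.01). Among them S100A9 (2.24) and KRT13 (1.52) lay above 0 and KLF4 (-1.10) below. Integrins had 0.06 (98.6), also without a direction, with ITGB4 at 1.04 and ITGB1 at -0.69. Mesenchymal genes had 0.23 (93.8), with the actin-binding TAGLN at 1.61, SPARC at 1.12 and the receptor kinase AXL at -1.73.

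Signalling and stress lists divided at 12 Gy. Immediate early genes, which growth factors and stress induce within minutes, had a median of -0.90 (percentile 0.0), with 11 of 14 below 0, FOSL1 at -1.52, MYC at -1.19, EGR1 at -1.04 and JUND at 1.26. Secreted inflammatory factors had -0.36 (1.9), with CXCL8 reads in 2.17% (0.264 to 7.63) of 12 Gy cells and 31.7% (18.1 to 48.1) of 0 Gy cells, and IL6 at -1.65. Interferon-stimulated genes had 0.22 (91.6), with IFI6 at 1.45 and IFIT2 at -0.88, but -0.05 for members with a mean of at least 20, so no direction is given. MHC class I presentation genes had 0.17 (99.5), with HLA-B at 1.05, HLA-E at 0.75 and B2M at -0.37. NRF2 and antioxidant genes had -0.50 (3.0), with the ferritin chain FTH1 at -1.28, TXNRD1 at -1.10 and ME1 at -1.02. Hypoxia and glycolysis genes had -0.36 (14.9), with LDHA at -1.03 and TPI1 at -0.90. Stem-cell associated genes had -0.74 (0.2) but were split. Of 8 members 5 lay below 0, 2 of them by at least 2-fold, with ALDH1A3 at -1.15. The 3 above 0 were each at least 2-fold higher, among them NGFR (1.22) and POU5F1 (1.43, or 0.38 in gene-rich cells). Notch genes had 0.34 (84.1), led by HES2 (1.19) and DLL1 (1.15), and Wnt genes 0.47 (97.2), with LEF1 at 1.15 and WNT5A at 1.14, but relative values of 0.07 to 0.49 over the scalings. Heat shock and unfolded protein response genes had -0.32 (36.8), with DNAJB1 at -0.85.

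Lists that served as references at 12 Gy gave medians of -0.36 (percentile 60.6) for reference genes, -0.28 (96.6) for cytosolic ribosomal proteins and -0.48 (37.6) for mitochondrially encoded genes. Among them TUBA1B had -1.34, RPS2 -1.09, MT-CO3 -1.17 and MT-ATP8 1.54. Markers of other cell types were scarce. Of the fibroblast, leukocyte, and endothelial and erythroid markers, 3, 3 and 2 genes were expressed, with medians of 0.51 (74.4), 1.00 (93.4) and 0.39 (52.8). CD74, the invariant chain of MHC class II, which carcinoma cells can also express, was the most abundant of them with 80.3 and 80.9 normalized counts at 12 and 0 Gy. The values are from 1 sample per dose, and a difference between cultures or library batches would enter them in full.

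**Figure D2:**
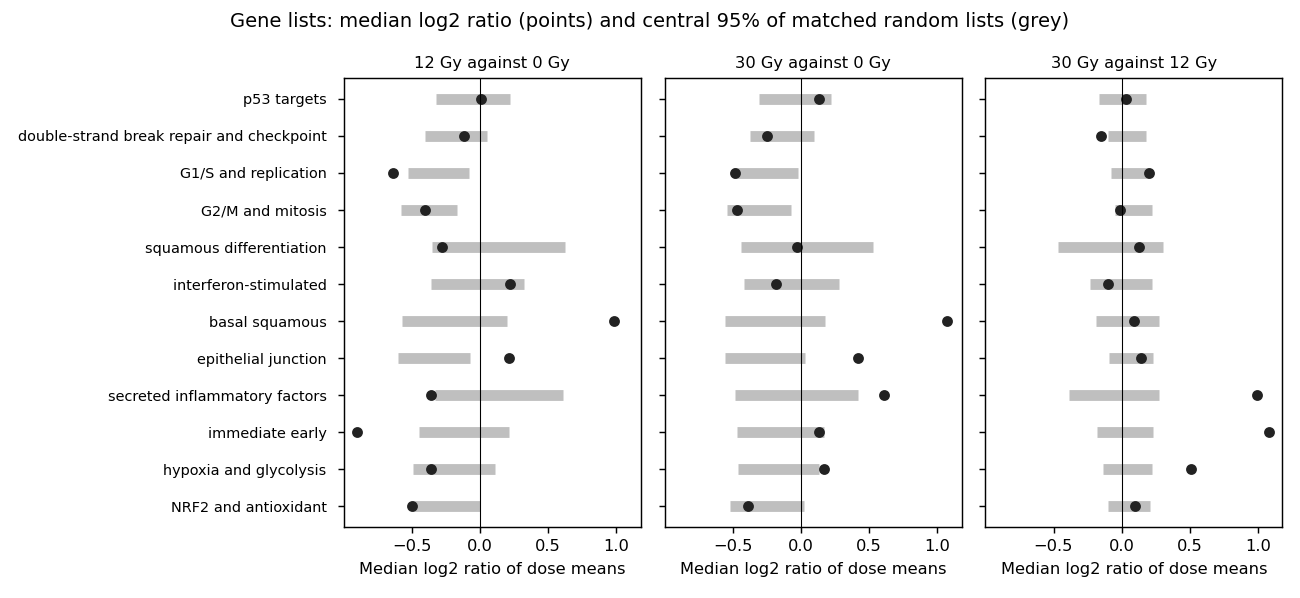
Median log2 ratio of dose means for 12 gene lists in the 3 comparisons, where each point is a list median and the grey bar spans the central 95% of 10000 matched random lists. At 12 Gy against 0 Gy the medians of G1/S genes (-0.64) and immediate early genes (-0.90) lie below their grey bars, and both stayed lower than the median expressed gene under the 6 scalings.

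Cells at 30 Gy were then compared with unirradiated cells, which contrasts the highest cumulative dose with none. Stress keratins, the vitamin D catabolic enzyme CYP24A1, the stress cytokine GDF15 and basal squamous genes were higher at 30 Gy, and several genes of sterol synthesis and the receptor kinase AXL were among the lowest. CYP24A1 (chromosome 20, 54153449 to 54173973) had a mean of 43.2 normalized counts at 30 Gy, 15.9 at 12 Gy and 1.97 at 0 Gy, a log2 ratio of 3.90 between 30 and 0 Gy. It had reads in 42.7% of cells (32.3 to 53.6) at 30 Gy and 19.5% (8.82 to 34.9) at 0 Gy. GDF15 had 46 against 4.21 normalized counts (3.17). A separate set of genes had no reads at all at 30 Gy and is described after the others.

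All 12 highest genes at 30 Gy were also the 12 highest in gene-rich cells. These were 88 of 89 cells at 30 Gy and all 41 at 0 Gy, so this check could change little. KRT6A had 145.6 ± 424 normalized counts at 30 Gy and 9.2 ± 19.3 at 0 Gy (3.84), although the share of cells with reads was 36% (26.1 to 46.8) and 39% (24.2 to 55.5). KRT17 (3.17), INHBA (2.99), MAB21L3 (2.92) and S100A9 (2.58) were among the highest. The others were NPIPB4 (3.05), a member of a family of near-identical copies whose reads are uncertain, the microfibril gene MFAP5 (2.94), SLC2A3 (2.84), the mitochondrial import subunit TOMM5 (2.62) and the secreted glycoprotein STC1 (2.51). SLC2A3 had 142.1 ± 328 normalized counts against 19 ± 35.3.

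Over 100000 bases away from genes low at 30 Gy, the 12 lowest genes were the same in gene-rich cells, a check that again left out 1 cell. The methionine salvage enzyme ADI1 had 6.34 ± 7.64 normalized counts at 30 Gy, 42.2 at 12 Gy and 81.7 ± 53.3 at 0 Gy (-3.49), and UTP4, a ribosome assembly factor, had 19.4 ± 17.4 against 177.2 ± 75.7 (-3.12). ADI1 and UTP4 were also over 4-fold lower than at 12 Gy, short of the 8-fold definition of genes low at 30 Gy. At 4-fold, 231 genes were lower at 30 Gy than at both other doses, against 33 for 0 Gy and 3 for 12 Gy. Of the 231, 74.5% had another within 100000 bases. Whether ADI1 and UTP4 belong to that pattern was not tested. Lipid genes followed, with STARD4 (-2.46), SCD (-2.30), INSIG1 (-2.26), SC5D (-1.89) and ACAT2, which makes the first intermediate of the sterol pathway (-1.75). AXL had 249 ± 216 normalized counts at 30 Gy and 919 ± 574 at 0 Gy (-1.88). C4BPB (-2.52), TSPAN12 (-2.15), TVP23B (-1.97) and CLPTM1L (-1.92) were the remaining genes, although CLPTM1L lies between SLC12A7 and LPCAT1 on chromosome 5, which were both low at 30 Gy.

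Medians of G1/S and G2/M genes at 30 Gy lay below 0 but within the central 95% of matched random lists. G1/S genes had a median of -0.48 (percentile 4.0), with 19 of 20 below 0, CDC6 at -0.82, RRM2 at -0.77 and CDT1 at 1.36. G2/M genes had -0.47 (8.9), with 18 of 20 below 0, CDK1 at -0.94 and CCNB1 at -0.87. Relative to the median expressed gene these lists ran from -0.43 to -0.34 and from -0.42 to -0.34 over the scalings. CDK inhibitor and senescence genes had 0.33 (98.8), with IGFBP3 at 1.93, CDKN1A at 0.49 and LMNB1, whose loss accompanies senescence, at -0.75. Replication-dependent histones had 0.09 (74.5).

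The p53 targets had a median of 0.13 (percentile 91.7) at 30 Gy, with 15 of 23 above 0 and relative values of 0.18 to 0.22, SESN2 at 0.85, TP53INP1 at 0.81 and CCNG1 at -1.12. Double-strand break repair and checkpoint genes had -0.25 (19.5), with 20 of 26 below 0, relative values of -0.26 to -0.17, LIG4 at -1.46 and NBN at -0.76. Pro-apoptotic genes had -0.34 (7.2), with CYCS at -1.06 and BIK at 0.83. Anti-apoptotic genes had -0.23 (39.6), with BCL2 at -0.63.

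Basal squamous genes had a median of 1.07 (percentile 100) at 30 Gy, with 9 of 11 above 0, TP63 at 2.58, KRT5 at 2.17 and ITGA6 at 1.46. TP63 had reads in 22.5% (14.3 to 32.6) of 30 Gy cells. Stress keratins had 3.17 (100). Epithelial junction genes had 0.42 (100), with KRT19 at 2672 ± 2570 against 996 ± 458 normalized counts (1.42) and the plakoglobin gene JUP at 1.09, while TJP1 (-5.59) was itself at least 8-fold lower at 30 Gy than at both other doses and OCLN (-2.27) lay near such a gene. Mesenchymal genes had 0.54 (99.9), with SPARC at 1.17 but VIM at -1.08 and AXL low. Integrins had 0.21 (99.7), with ITGB4 at 1.10, ITGB6 at 0.87 and ITGB1 at -0.83. Squamous differentiation genes had -0.03 (36.1) and no direction (relative values of -0.19 to 0.23), with CNFN at 0.85 and TGM1 at -0.41.

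Secreted inflammatory factors had a median of 0.61 (percentile 99.8) at 30 Gy, with 7 of 8 above 0 and the collagenase MMP1 at 1.06. The list also holds the NF-kB inhibitors TNFAIP3 (1.16) and NFKBIA (0.68), which are not secreted. The cytokine IL6 was the member below 0 (-0.66), with means of 19.3 at 30 Gy and 30.7 at 0 Gy in gene-rich cells. Hypoxia and glycolysis genes had 0.17 (98.7), with 12 of 18 above 0. NDRG1 (2.12) and CA9 (1.69) lay above 0, and BNIP3 (-0.70) and TPI1 (-0.58) were among the 6 below. Immediate early genes had 0.13 (95.6), with FOSB at 2.62 and JUNB at 0.87. Interferon-stimulated genes had -0.18 (27.5), which was 0.17 in odd-numbered and 0.16 in even-numbered cells and is given no direction. NRF2 and antioxidant genes had -0.39 (15.4), with ME1 at -1.39 and the cystine transporter SLC7A11 at -1.01. Stem-cell associated genes had -0.61 (3.0), with ABCG2, a drug efflux pump, at -1.56 and NGFR at 1.80. Notch genes had 0.36 (90.8), with NOTCH1 at 1.59, and Wnt genes 0.43 (99.2), with relative values of 0.06 to 0.48, TCF7 at 0.71 and DKK1 at -0.74. Heat shock and unfolded protein response genes had -0.26 (37.7), with DDIT3 at 1.04.

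Reference genes at 30 Gy had a median of -0.31 (percentile 51.3), mitochondrially encoded genes -0.52 (16.0) and cytosolic ribosomal proteins 0.05 (100). The 3 expressed fibroblast markers had 1.21 (99.5), but 0.64 in gene-rich cells and relative values of 0.33 to 1.26, led by PDGFRB at 1.46 in all and 0.64 in gene-rich cells. The single expressed leukocyte marker, CD74, had -0.22 (51.4), and the endothelial and erythroid markers had 0.36 (68.8). COL1A1 and COL1A2, the most abundant fibroblast markers, had means of 9.95 and 15.5 normalized counts at 30 Gy.

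A group of abundant genes had no reads in any 30 Gy cell. Of 10179 genes with reads in over 50% of cells at both other doses, 1.55% had none at 30 Gy. The same count for 0 Gy gave 7 of 9364 genes (0.07%), and for 12 Gy 0 of 9322. For each, 0 of 89 cells allows a share of up to 4.06% of cells with reads. The 12 lowest genes of the comparison all belonged to this group. RPS18, a protein of the small ribosomal subunit (chromosome 6, 33272010 to 33276510), had 121202 reads (120521 to 121886) at 0 Gy and 0 (0 to 4) at 30 Gy, at least 19627-fold lower against a floor of 3 reads over the dose. TUBB, a beta-tubulin (chromosome 6, 30720201 to 30725426), was at least 19497-fold lower, and RPL7A, of the large ribosomal subunit (chromosome 9, 133348214 to 133351426), at least 10733-fold. CLIC1, YWHAE, SLC16A1, PSMC4, RPS25, SURF4, SMARCB1 and RPS9 were at least 8561-, 8046-, 6972-, 6422-, 4189-, 3883-, 3860- and 3002-fold lower.

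Genes without reads or nearly so at 30 Gy clustered in the genome. By a definition chosen after the values were seen, 214 genes were at least 8-fold lower at 30 Gy than at both other doses, with 15 and 1 such genes for 0 and 12 Gy. The longest block lay on chromosome 6 between 28903002 and 33418317, where 67 of 69 genes with at least 10 normalized counts at both other doses were that low. MHC class I presentation genes lie largely there and had a median of -5.29 (percentile 0.0), or -6.66 with genes without reads at their bound. PSMB8 was at least 1045-fold and HLA-E at least 959-fold lower, HLA-B had 3 reads against 6267 and TAPBP 1 read against 8264. NLRC5, the transactivator of these genes, was the only member outside such regions, at 1.22. The checkpoint adaptor MDC1 (at least 293-fold), the immediate early gene IER3 (257-fold), the chaperones HSPA1A (622-fold) and HSPA1B (226-fold) and the Notch ligand DLL1 (31.6-fold) were also lower by at least these bounds. These values are reported as read counts of the deposited table, and no direction of expression is taken from them.

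**Figure D3:**
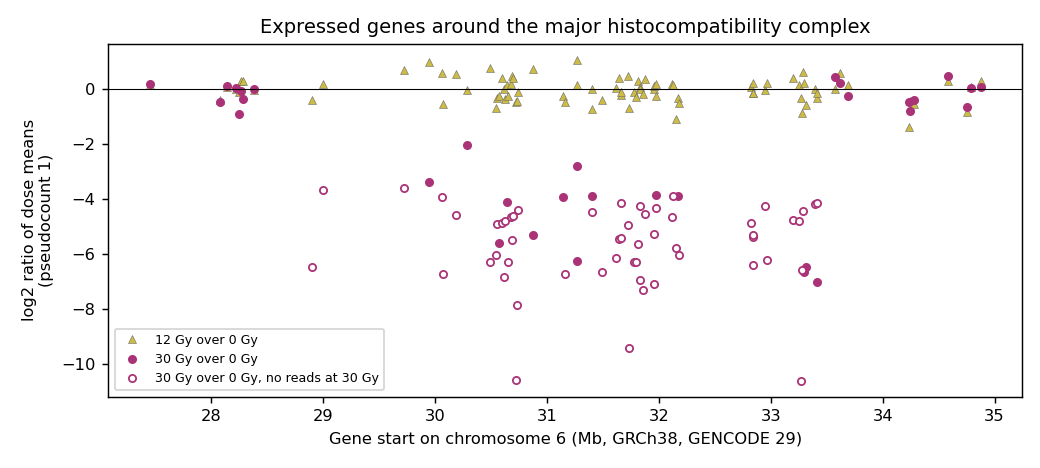
Log2 ratio of dose means by gene start on chromosome 6 around the MHC (GENCODE 29, GRCh38), where triangles are 12 Gy against 0 Gy, circles are 30 Gy against 0 Gy and open circles are genes without reads at 30 Gy. Between 28903002 and 33418317, 67 of 69 genes were at least 8-fold lower at 30 Gy than at both other doses.

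Cells at 30 Gy were last compared with cells at 12 Gy, which asks what differed between the irradiated populations. Immediate early genes, secreted inflammatory factors and hypoxia and glycolysis genes were higher at 30 Gy. FOS, a subunit of the AP-1 transcription factor (chromosome 14, 75278774 to 75282230), had 168.2 ± 212 normalized counts at 30 Gy, 65.4 ± 87 at 12 Gy and 120.5 at 0 Gy (1.35). AREG had 95.3 ± 393 against 20.4 ± 38 (2.17), DUSP1 224 ± 234 against 57.1 ± 97.2 (1.95) and MYC, with 63.5 at 0 Gy, 65.3 ± 80.4 against 27.3 ± 28.8 (1.23). Immediate early genes had a median of 1.08 (percentile 100), with 13 of 14 above 0, FOSB at 1.49 and ATF3 at 1.39. The exception, IER3, had no reads at 30 Gy.

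Of the 12 highest genes at 30 Gy against 12 Gy, 6 were also among the 12 highest in gene-rich cells. STC1 had 48.7 ± 109.2 normalized counts against 11 ± 27.4 (2.05), KRT6A had a log2 ratio of 1.87, TNFAIP3 1.52 and JUNB 1.27. The aminopeptidase ANPEP (1.22), the transcription factor NKX2-5 (1.22), the prostaglandin E synthase PTGES (1.19) and the ubiquitin ligase RNF126 (1.16) completed the set. In gene-rich cells MYC had 1.16, JUNB 1.09, ANPEP 1.07, RNF126 1.05, PTGES 1.03 and NKX2-5 0.94, while AREG (2.35) and STC1 (2.21) were higher than in all cells. The 12 lowest were the same 12 genes without reads at 30 Gy, led by RPS18 (at least 15469-fold lower) and TUBB (at least 14062-fold). Over 100000 bases away from genes low at 30 Gy, SPINK9 (-5.42), AIFM3 (-3.80), TMED2-DT (-3.45), TMEM212 (-2.65), UGDH-AS1 (-1.74), HELLPAR (-1.74) and CFAP54 (-1.69) were among the lowest, but had -0.65, -0.52, -0.86, -0.29, -0.38, -0.42 and -0.60 in gene-rich cells. The other 5, which were also lowest in gene-rich cells, were ADI1 (-2.56), the RNA-binding protein TAF15 (-2.42), CYP1A1, which oxidises aromatic hydrocarbons (-2.35), UTP4 (-2.35) and the calcium channel TRPV6 (-1.98). Of these, ADI1 and UTP4 were over 4-fold lower than at 0 Gy too, with the limit given above. IL32 (-1.72), NBPF1 (-1.31), TAMM41 (-1.30) and HERC2 (-1.17) entered in gene-rich cells. Except for IL32, the other genes were also lower at 30 Gy than at 0 Gy, short of 4-fold. Gene-rich means at 0, 12 and 30 Gy were 14.1, 27.5 and 4.57 for TAF15 and 14.4, 23.4 and 4.51 for TRPV6. They were 121.5, 97.3 and 38.5 for NBPF1 and 38.8, 41.3 and 16.2 for TAMM41. Whether these genes share the pattern of genes low at 30 Gy was not tested either.

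Hypoxia and glycolysis genes had a median of 0.51 (percentile 100) at 30 Gy against 12 Gy, with 18 of 18 above 0, relative values of 0.50 to 0.59, NDRG1 at 1.84, CA9 at 1.77, the glucose transporter SLC2A1 at 0.80 and the peptide hormone ADM at 0.76. Secreted inflammatory factors had 0.99 (100), with relative values of 0.45 to 1.05, MMP1 at 2.69 and CXCL2 at 2.17, while TNF, in the chromosome 6 block, had no reads at 30 Gy and 86 at 12 Gy. G1/S genes had 0.20 (97.3), with 19 of 20 above 0, CCNE2 at 0.62 and SLBP at 0.51. Replication-dependent histones had 0.34 (98.8), with relative values of 0.09 to 0.34 and H2AC6 at 1.34. Cytosolic ribosomal proteins had 0.34 (100), with RPL8 at 0.69, and reference genes 0.23 (93.8), with GAPDH, also a member of the hypoxia and glycolysis list, at 0.72. Double-strand break repair and checkpoint genes had -0.15 (0.4), and -0.06 in gene-rich cells, with ATM at -0.66. Interferon-stimulated genes had -0.10 (16.5), with IFIT3 at -0.54, and epithelial junction genes 0.14 (74.8), with JUP at 0.51 and ESRP1 at -0.58.

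Smaller medians at 30 Gy against 12 Gy were 0.09 (percentile 61.3) for basal squamous genes, with KRT5 at 1.76 and KRT15 at -0.52, and 0.14 (82.4) for CDK inhibitor and senescence genes, with relative values of 0.01 to 0.14 and CDKN1A at 0.45. They were 0.10 (68.8) for NRF2 and antioxidant genes, 0.18 (90.9) for pro-apoptotic, 0.24 (93.5) for anti-apoptotic, 0.14 (80.4) for heat shock and unfolded protein response genes and 0.08 (38.0) for mitochondrially encoded genes. Without a direction over the scalings were p53 targets (0.03, 59.3), G2/M genes (-0.01, 8.1), squamous differentiation genes (0.13, 84.7), stress keratins (0.04, 52.3), mesenchymal genes (-0.11, 17.7), integrins (0.06, 44.2), stem-cell associated genes (-0.06, 30.5), Notch genes (0.05, 68.2) and Wnt genes (-0.01, 47.2). KRT13 (-1.56), ZEB1 (-1.10), TAGLN (-0.87) and CD24 (-0.77) were lower among them, and NOTCH1 (1.25) and KLF4 (0.98) higher. MHC class I presentation genes had -5.15 (0.0), or -7.29 with genes without reads at their bound. Fibroblast, leukocyte, and endothelial and erythroid markers had 0.71 (99.4), -0.21 (30.2) and -0.02 (61.2), the first 0.16 in gene-rich cells and 0.06 to 0.75 in relative values.

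The median coefficient of variation over cells of 5992 genes was 0.54 at 0 Gy, 0.81 at 12 Gy and 0.78 at 30 Gy, with 0.67, 0.85 and 0.84 after thinning to 1 depth and 0.54, 0.70 and 0.77 in gene-rich cells. The per-cell mean of log2 normalized counts of G1/S genes was 6.26 ± 0.97, 5.10 ± 1.49 and 5.39 ± 1.30 at 0, 12 and 30 Gy, and that of G2/M genes 6.86 ± 1.52, 5.78 ± 2.29 and 5.83 ± 2.17. For basal squamous genes it was 4.54 ± 0.42, 4.86 ± 0.92 and 5.00 ± 0.92, and for immediate early genes 4.50 ± 0.84, 3.40 ± 1.12 and 4.21 ± 0.84. The p53 targets had 3.74 ± 0.43, 3.37 ± 0.77 and 3.37 ± 0.57, but 1.35, 1.37 and 1.38 after thinning. Thinning gave 3.14, 2.63 and 2.83 for G1/S genes and 1.95, 1.45 and 2.03 for immediate early genes.

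**Figure D4:**
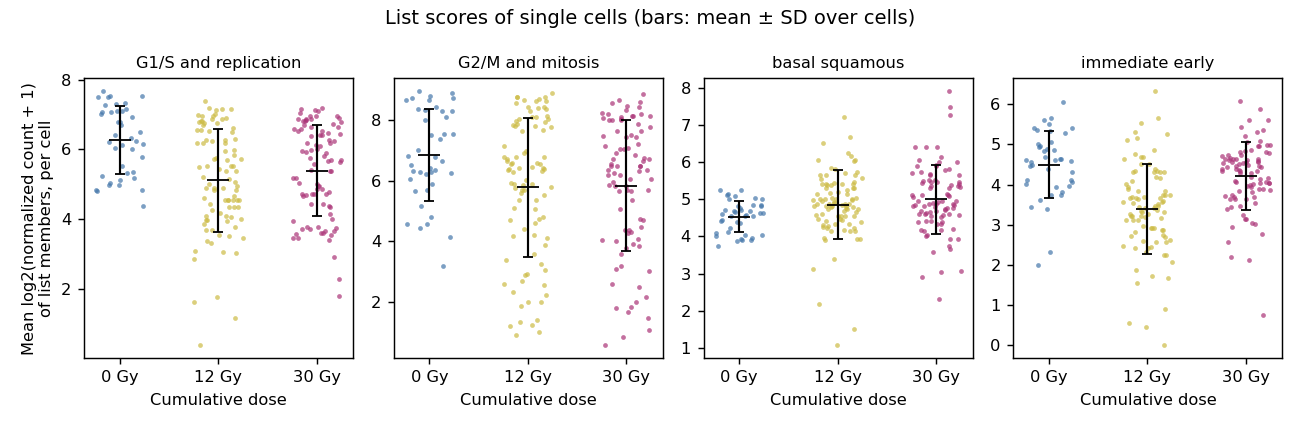
Mean log2(normalized count + 1) over the members of 4 gene lists in each cell, by dose, where each point is 1 cell and the bars give the mean and SD over cells. Immediate early genes had means of 4.50, 3.40 and 4.21 at 0, 12 and 30 Gy.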

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

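The alternatives of summed reads, median-of-ratios factors and leaving out genes near those low at 30 Gy, and gene-rich cells for single genes and for the coefficient of variation, were chosen after seeing the data. No paired analysis was possible because no test was run and the replicate numbers at 12 Gy name the same columns. The spread of a list median over 4 subsets of cells was as large as some of the values. For G2/M and mitosis, 12 Gy against 0 Gy, it was 0.67 around -0.40, for G2/M and mitosis, 30 Gy against 0 Gy, 0.48 around -0.47, and for G1/S and replication, 12 Gy against 0 Gy, 0.52 around -0.64. Median-of-ratios factors took the first of these medians to 0.04. Depth limits what can be seen at 30 Gy, where the floor of 3 reads lies at 0.0791 normalized counts. The causes of the changes below were not tested.

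Scaling each cell to its total gave medians at 12 Gy against 0 Gy of 0.30 for p53 targets, 0.14 for double-strand break repair and checkpoint genes and 0.46 for interferon-stimulated genes. The values at 30 Gy against 0 Gy were 0.39 for p53 targets, -0.21 for G1/S genes, and reversed values of 0.02 for double-strand break repair and 0.08 for interferon-stimulated genes. Median-of-ratios factors gave 0.51 for p53 targets, 0.35 for double-strand break repair, 0.20 for squamous differentiation and 0.61 for interferon-stimulated genes at 12 Gy against 0 Gy. For 30 Gy against 0 Gy they gave 0.48 for p53 targets, -0.11 for G1/S genes, and reversed values of 0.09 for double-strand break repair and 0.15 for interferon-stimulated genes. Double-strand break repair genes had -0.33 at 30 Gy against 12 Gy.

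Thinning to 1 depth gave 0.37 for p53 targets, 0.16 for double-strand break repair and 0.21 for squamous differentiation genes at 12 Gy against 0 Gy. At 30 Gy against 0 Gy the values were 0.38, -0.03 and 0.41 for these lists, -0.18 for G1/S genes and a reversed 0.17 for interferon-stimulated genes. It gave 8374, 8700 and 8243 genes detected at 0, 12 and 30 Gy, against 8051, 7768.5 and 7374 genes at 10 or more normalized counts. The median coefficient of variation was 0.67 at 0 Gy and 0.84 at 30 Gy after thinning, and 0.70 at 12 Gy in gene-rich cells.

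The ratio of summed reads gave 0.29 for p53 targets, 0.15 for double-strand break repair, 0.10 for squamous differentiation and 0.56 for interferon-stimulated genes at 12 Gy against 0 Gy, and reversed H2BC12 to 0.05. At 30 Gy against 0 Gy it gave 0.39 for p53 targets, -0.08 for double-strand break repair, -0.15 for G1/S genes and a reversed 0.13 for interferon-stimulated genes. Averaging log2 values over cells gave -0.27 for p53 targets, -0.44 for double-strand break repair, -1.21 for G1/S and 0.03 for interferon-stimulated genes at 12 Gy against 0 Gy. At 30 Gy against 0 Gy it gave -0.52 for double-strand break repair, -0.99 for G1/S, -1.08 for G2/M and -0.37 for interferon-stimulated genes. It reversed p53 targets to -0.22, H1-2 to -0.40, H2BC4 to -0.26 and TRIB3 to -0.11. At 30 Gy against 12 Gy it gave -0.30 for interferon-stimulated genes and reversed GRHL3 to -0.01. Trimming 10% of cells at each end gave -0.25 and 0.01 for p53 targets at 12 Gy and 30 Gy against 0 Gy, and reversed H2BC4 at 30 Gy to -0.19.

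Interferon-stimulated genes at 12 Gy against 0 Gy had 0.37 in odd-numbered cells, 0.11 in even-numbered cells, 0.11 with a pseudocount of 10 and a reversed -0.05 for members with a mean of at least 20. In the comparison of 30 Gy with 0 Gy they reversed to 0.17 in odd-numbered and 0.16 in even-numbered cells, and had -0.01 without a filter on members and -0.01 without genes near those low at 30 Gy. Squamous differentiation genes had 0.67 in odd-numbered cells and 0.39 without a filter at 12 Gy, and 0.98 and 1.16 at 12 Gy and 30 Gy for members with a mean of at least 20.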

Other observations

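The length and GC test of the sterol genes was fixed before its result was seen, and the gene lists and all other tests in this part were chosen after seeing the values. Sterol pathway genes were lower at both irradiated doses, under the 6 scalings tried. The lists of these 2 paragraphs were built around genes already seen among the lowest or highest, so their medians describe the members and are not independent support. The sterol median log2 ratio was -1.20 at 12 Gy against 0 Gy, with 19 of 20 genes below 0, and -1.26 at 30 Gy against 0 Gy, with 20 of 20 below 0. SQLE, which oxidises squalene, had means of 81.3, 21.8 and 30.2 normalized counts at 0, 12 and 30 Gy, and IDI1, an isomerase of the pathway, 203, 69.7 and 71.5. At 30 Gy against 12 Gy the list had 0.04, with no direction over the scalings. The 13 sterol enzyme genes that the rule for named genes had not picked had medians of -1.12, -1.05 and 0.04 in the 3 comparisons. Without the 2 of them that were low at 30 Gy or near such genes, the medians were -1.12, -0.86 and 0.04. Fatty acid synthesis and desaturation genes had -0.81, -0.91 and 0.17, with SCD among them, although FASN, the fatty acid synthase, was higher with 28, 32.4 and 44 normalized counts. LSS and ACACA, in these lists, were themselves among the genes at least 8-fold lower at 30 Gy than at both other doses.

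The 4 metallothioneins, which bind zinc and copper, had medians of 1.98, 2.04 and 0.03, with MT1X and MT1F, already seen among the highest genes, in the list. MT2A had means of 185.6, 516 and 519 normalized counts at 0, 12 and 30 Gy, and MT1E 45.4, 162.9 and 172.3. EGFR ligands, which include EREG and AREG, already seen among the lowest genes, had -1.10 at 12 Gy against 0 Gy, -0.65 at 30 Gy against 0 Gy and 0.20 at 30 Gy against 12 Gy. TGFA had 50.4, 27.9 and 31.9 normalized counts, and HBEGF 18.8, 8.21 and 9.56.

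Of the 214 genes at least 8-fold lower at 30 Gy than at both other doses, 59.8% had no reads there, and 15 blocks of at least 3 genes held 72% of them. Lower depth at 30 Gy is argued against by the reads that the other doses predicted for these genes at the 30 Gy depth. They were at least 390 per gene with a median of 1273, where the median observed was 0. Thinning every cell to 100000 reads left 212 genes (99.1%) at least 8-fold lower, but thinning keeps expected shares of reads and adds little here. Loss or silencing in the irradiated cells is argued against for the set, since it held 4 genes of the cytosolic ribosome without reads, RPS18, RPL7A, RPS25 and RPS9, for which the other doses predicted 46408, 24129, 9566 and 6724 reads. A candidate explanation is that reads of some regions were aligned or counted differently in the 30 Gy libraries, as 72.0% of the genes had another within 100000 bases, against at most 15.0% (median 5.6%) in 1000 draws of 214 from 8423 genes. Whether a reference with alternate copies of regions such as the MHC was used for this dose could not be tested, and dose and library batch cannot be told apart.

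Immediate early genes were lower at 12 Gy than at both other doses. The sparse cells at 12 Gy are argued against as the cause, since in gene-rich cells the list lay at -0.84 against 0 Gy relative to all expressed genes, and 30 Gy lay 1.03 above 12 Gy. Thinning gave -0.72 and 0.98, but it keeps each gene's expected share of a cell's reads, so it cannot decide on depth. An effect of the dose on these genes, and a difference in handling of the culture or the library batch, which may act on genes induced within minutes, stay open and untested.

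The lower sterol enzyme genes at both irradiated doses were weighed in the same way. A trend of the ratio with gene length and GC content is argued against, since the 13 genes, all with values, kept medians of -1.08 at 12 Gy and -0.74 at 30 Gy once it was removed. Thinned medians were -0.96 and -0.99 relative to all expressed genes, but thinning cannot decide on depth, for the reason given above. The 30 Gy values of both tests include 2 genes that were low at 30 Gy or near such genes. Without these 2 the 30 Gy median was -0.86 before the trend was removed, and neither test was repeated without them. A dose effect on sterol synthesis could account for these values, as could different serum or cell density in the cultures, and with 1 sample per dose none of these was tested.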
